A study of Mus musculus with 9 samples.

How the data were processed

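PolyA RNA of C2C12 cells, a mouse myoblast line, was sequenced on a HiSeq2500 from a Cry1 knockdown, a Cry2 knockdown and a control. Each was collected at days 0, 3 and 5 of differentiation, with 1 library for each of the 9 combinations. Per the labels, growth medium held 10% fetal bovine serum and differentiation medium 5% horse serum and 1% insulin, transferrin and selenium. How the knockdowns were made is not stated in the labels. The values are raw gene counts as deposited by the authors, made per the labels with CASAVA 1.8, HISAT2 2.0.2 on mm10 and featureCounts 1.4.6 of Subread. The files hold 47728 genes, of which 23515 have a count in some library. Library totals ran from 4731020 to 6412279 counts, and a count of 0 allows up to 3 counts, or 0.468 to 0.634 CPM by library. Such floors cover counting error only.

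Counts were normalised with TMM and tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by quasi-likelihood F tests, with genes filtered by filterByExpr and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The genotype and day comparisons came from an additive fit of genotype and day over all 9 libraries (13094 genes, 4 residual degrees of freedom). The differentiation responses came from a fit of genotype by stage, day 0 against days 3 and 5, with a shared term for day 5 against day 3 (13608 genes, 2 residual degrees of freedom). Standard errors were the absolute log2 fold change divided by the square root of F. CPM values are scaled by the TMM factors. Within a day, log2 ratios used a prior count of 1, and a list's median was set against 10000 random lists matched on size and on expression in 50 bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the remaining work.

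Of 29 gene lists, the 27 with at least 5 measured members were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the lists within a comparison. A list is said to pass by the first of these unless another is named. The lists were myogenic transcription factors, myoblast fusion, sarcomere, calcium handling and excitation-contraction coupling, acetylcholine receptor and neuromuscular synapse, muscle energy metabolism, G1 cyclins, kinases and E2Fs, and CDK inhibitors and pocket proteins. Further lists were DNA replication, mitosis, E-box clock repressors and outputs, other clock genes, reserve cell and Notch, extracellular matrix and fibroblast, smooth muscle and TGF-beta or YAP targets, adipocyte, osteoblast, and endothelial and blood cell. The rest were interferon response, p53 targets, unfolded protein and amino acid stress, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, glycolysis and hypoxia, immediate early and growth factor response, insulin-like growth factor axis, muscle atrophy, and mitochondrially encoded genes.

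The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Named genes were Cry1, Cry2, Ccnd1, Tmem176b, Tmem176a and Bclaf1, then the 8 largest rises and 8 largest falls per comparison. These had to pass the threshold, have a mean of at least 1 CPM and move the same way at every day or in every genotype, and unnamed gene models were skipped. Where none passed, the 5 genes of lowest p were named. Up to 4 members were named per list. Some genes that this rule selects are withheld for evaluation and are not reported here.

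Alternatives were size factors by RLE, no filter on low counts, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, fits without the day or genotype term, only the 6 libraries compared, each day, genotype or library left out in turn, and a prior count of 5 within days. Fits without mitochondrially encoded genes and pseudogenes were added after the data were seen. The calls were also counted for the other splits of the 6 libraries compared. Gene coordinates and transcripts came from a GENCODE annotation of mm10. The 50-base words of the longest annotated transcript of each gene were searched, on both strands, in the longest transcripts of all other genes. All 16240 7-base words of 3' UTRs were tested for lower expression in each knockdown, against 1000 permutations. Shorter transcripts and genome sequence outside annotated genes were not searched.

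Tested on simulated data of this depth, the fit called 0 genes where none was changed. The simulated libraries held no culture difference shared by the days of a genotype. It recovered 41.8%, 86.6% and 100% of genes changed 1.5-fold, 2-fold and 4-fold in a genotype comparison, and 5.97%, 37.3% and 92.4% in a differentiation response. Of the calls in the genotype comparison, 2.28% fell on unchanged genes. The changed genes were drawn only from those of higher expression, so recovery at low expression was not measured. Every simulated gene had the spread of the trend at its expression, without a spread of its own. No library was left out except in the alternatives.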

Results

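The data are counts from sequencing of polyA RNA from C2C12, a mouse myoblast line that fuses into myotubes after a change to horse serum. A Cry1 knockdown, a Cry2 knockdown and a control culture were collected at days 0, 3 and 5 of differentiation, and each of the 9 combinations of genotype and day has 1 library. Cry1 and Cry2 encode cryptochromes, the repressor proteins of the circadian clock. Total counts at days 0, 3 and 5 were 6412279, 6062366 and 5666697 in the control, 6402164, 6046946 and 6029574 in the Cry1 knockdown, and 5814077, 4731020 and 5613587 in the Cry2 knockdown. Of 13094 genes tested, each was compared between genotypes over the 3 days, or between days over the 3 genotypes, in an additive edgeR fit. No genotype and day has a replicate. The p-values therefore set a genotype difference against disagreement between days, or a day difference against disagreement between genotypes. In either case the spread was estimated over all 9 libraries, those outside the compared pair included. Differences within a day have no replicate check. The 3 libraries of a genotype are its 3 days, so n = 3 there counts days and not replicate cultures. A culture difference shared by the 3 days cannot be told apart from an effect of the knockdown.

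Each targeted gene was lowest in its own knockdown at every day. Cry2 (ENSMUSG00000068742, chromosome 2, 92403646 to 92434043, minus strand, mm10) had 7.27, 8.26 and 16.6 CPM (counts scaled to the library size) in the Cry2 knockdown at days 0, 3 and 5. It had 19.2, 39.7 and 48.9 CPM in the control and 28.8, 37.1 and 68.0 CPM in the Cry1 knockdown. It fell in the Cry2 knockdown by a log2 fold change of -1.74 ± 0.17 (SE, n = 3 libraries per genotype, adjusted p = 0.0138, edgeR). Cry1 (ENSMUSG00000020038, chromosome 10, 85131700 to 85185064, minus strand) had 8.30, 6.65 and 8.12 CPM in the Cry1 knockdown. It had 20.5, 15.8 and 17.4 CPM in the control and 13.1, 19.3 and 22.9 CPM in the Cry2 knockdown. It fell in the Cry1 knockdown by -1.22 ± 0.22 (n = 3, adjusted p = 0.0265). In the opposite knockdown, the fitted values were 0.02 ± 0.20 for Cry1 (adjusted p = 0.988) and 0.31 ± 0.15 for Cry2 (adjusted p = 0.295). The Cry2 call was lost without the day 3 or day 5 library of the Cry2 knockdown or the day 5 control (adjusted p up to 0.237). The Cry1 call was lost without any of the 6 Cry1 knockdown and control libraries (adjusted p up to 0.135).

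The series title also names cyclin D1, encoded by Ccnd1, Tmem176b, a membrane protein gene, and Bclaf1. Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925, minus strand) fell during differentiation, by -2.28 ± 0.24 from day 0 to day 3 (adjusted p = 7.6e-05). At day 3 it had 24.1 CPM in the Cry2 knockdown, 74.4 CPM in the control and 55.7 CPM in the Cry1 knockdown, while at day 0 the levels were 234, 241 and 237 CPM. Its difference between the Cry2 knockdown and the control over the 3 days did not pass the test (-0.60 ± 0.25, adjusted p = 0.374), nor did its response to differentiation (-1.0 ± 0.38, adjusted p = 0.797). Exons of LTO1 overlap 23.4% of the Ccnd1 exon bases, and the library kit named in the labels does not keep the strand. Tmem176b (ENSMUSG00000029810, chromosome 6, 48833818 to 48841496, minus strand) had 0.969, 1.91 and 0.378 CPM in the Cry2 knockdown and 2.35, 1.51 and 1.11 CPM in the control. The difference did not pass (-0.69 ± 0.49, adjusted p = 0.625). These are low counts, and the day 5 value of the knockdown lies under the floor of 0.534 CPM of that library. In the Cry1 knockdown Tmem176b had 5.63, 10.8 and 6.0 CPM and rose against the control by 2.11 ± 0.37 (adjusted p = 0.0247). Its neighbour and paralog Tmem176a (ENSMUSG00000023367, chromosome 6, 48840919 to 48847071, plus strand) rose there by 3.04 ± 0.49 (adjusted p = 0.0194). The ends of the Tmem176a and Tmem176b genes overlap, by 2.13% and 3.42% of their exon bases. The Tmem176b call was lost without the day 3 or day 5 library of the Cry1 knockdown or the control (adjusted p up to 0.145). The Tmem176a call was lost without these or the day 0 control (adjusted p up to 0.126). Bclaf1 (ENSMUSG00000037608, chromosome 10, 20312469 to 20344613, plus strand) did not pass in the Cry2 knockdown against the control (-0.09 ± 0.07, adjusted p = 0.65).

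**Figure D1:**
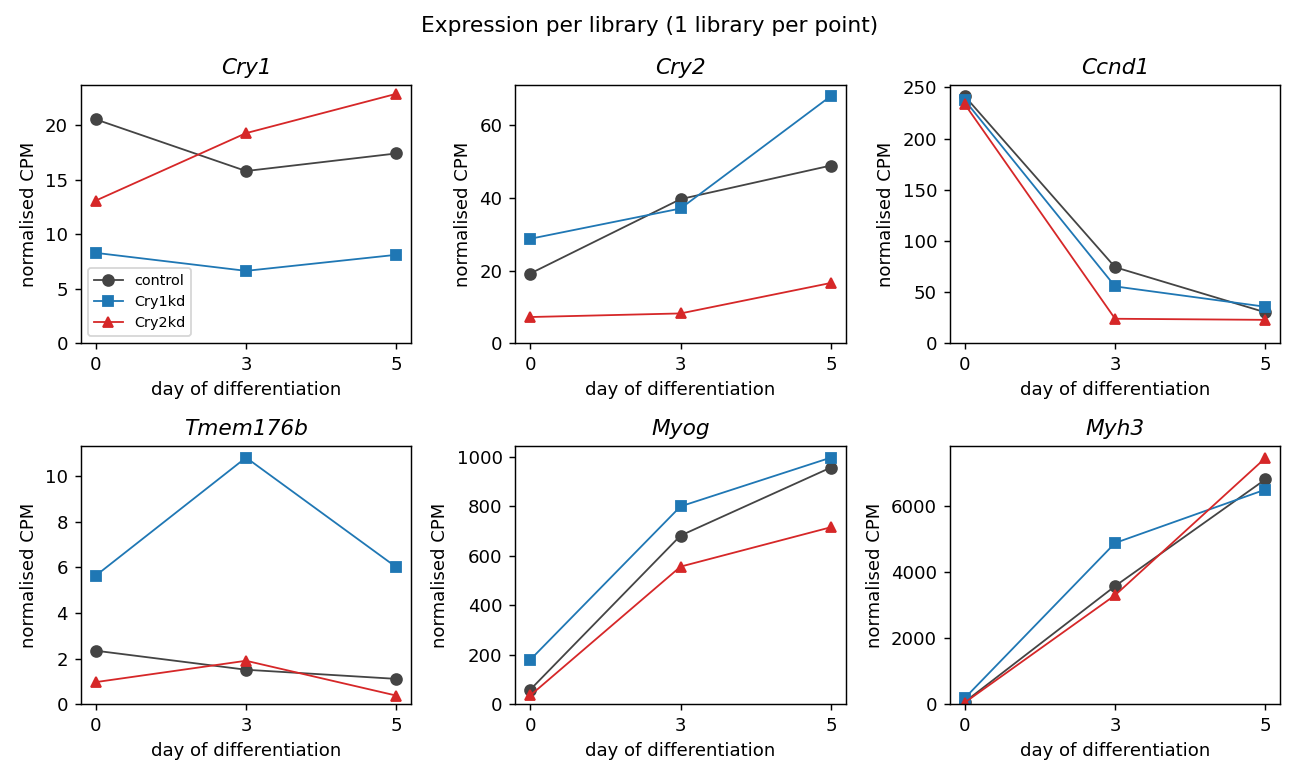
Normalised CPM of 6 genes on the vertical axes against the day of differentiation, with 1 library per point and 1 line per genotype. Cry1 and Cry2 lie lowest in their own knockdown at each day, Tmem176b is highest in the Cry1 knockdown, and Ccnd1 at day 3 is 24.1 CPM in the Cry2 knockdown and 74.4 CPM in the control.

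The comparison of the Cry2 knockdown with the control asks what loss of Cry2 changes across differentiation. Col23a1, a membrane-bound collagen gene, had the largest rise among the named genes, 3.27 ± 0.28 (n = 3 libraries per genotype, adjusted p = 0.00758), with 45.3 and 109 CPM in the knockdown at days 3 and 5 and 5.71 and 8.15 CPM in the control. Stmn4, a microtubule regulator, rose by 1.15 ± 0.14. Also higher were Adgrg1, an adhesion receptor, which rose by 1.10 ± 0.12, and Ndrg4, which rose by 0.69 ± 0.09. Besides Cry2, the kinase gene Csnk1g1 fell by -0.82 ± 0.10, the basement membrane collagen gene Col4a1 by -0.72 ± 0.09, and Sae1, a subunit of the SUMO-activating enzyme, by -0.52 ± 0.07. In all, 6 genes rose and 5 fell of 13094 tested, with 1604 at an unadjusted p under 0.05. Also called, and named after their values were seen, were Gm10123, at 213, 0 and 10.6 CPM in the Cry2 knockdown at days 0, 3 and 5, and Adh1, an alcohol dehydrogenase gene, which fell by -1.91 but was not lower at day 0. Csnk1g1, Col4a1, Sae1 and Cry2 each carry both of the words TCAGCCC and CAGCCCA in the 3' UTR, as does Ndrg4, which rose, though these words were picked out on the same fold changes. The share of all genes with both words was not counted. At least 1 of these words stands in the 3' UTR of 27.2% of all genes searched. The same holds for 4 of the 5 searched genes called lower and 2 of the 5 called higher. Col23a1, which rose, carries 1 word and Adh1, which fell, carries 0. The count was 6 without the day 3 library of the Cry1 knockdown, 17, 1 and 0 without the day 0, 3 and 5 libraries of the Cry2 knockdown, and 5, 3 and 1 without those of the control. Of the 9 named genes 0 passed in every one of these fits. The count with DESeq2 was 90, and with all genes that have a count it was 316.

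The lists of mitosis, DNA replication and G1 genes were lower in the Cry2 knockdown over the 3 days, but not all at day 5. Within days 0, 3 and 5 the median log2 ratio to the control was -0.26, -0.28 and -0.14 for mitosis, -0.34, -0.34 and 0.10 for DNA replication and -0.12, -0.31 and 0.04 for the G1 list. All 29 mitosis genes were lower, with a median log2 fold change of -0.23 (adjusted p = 8.2e-08), although 0 passed one by one and 2 fell when adjusted over the list alone. Among them Mki67, the proliferation marker Ki-67, had -0.34 ± 0.14 and Top2a, a topoisomerase, -0.24 ± 0.08, neither past the threshold, and the list had adjusted p = 0.258 with an estimated correlation. Of 30 DNA replication genes, 26 were lower and 0 passed, also over the list alone (median -0.23, adjusted p = 0.00163, and adjusted p = 0.831 with an estimated correlation). The list of G1 cyclins, kinases and E2Fs was lower by a median of -0.17, with 0 of 11 passing and 2 fallen when adjusted over the list alone (adjusted p = 0.00615, and adjusted p = 0.464 with an estimated correlation). Extracellular matrix and fibroblast genes were lower in 17 of 22 cases, with Col3a1 at -0.51 ± 0.16 and Col1a2 at -0.38 ± 0.09. There 0 passed and 5 fell when adjusted over the list alone (median -0.19, adjusted p = 0.000184, adjusted p = 0.256 with an estimated correlation, and 0.00231 by fry). Immediate early and growth factor response genes, of which Egr1 had -0.64 ± 0.13, had a median of -0.32 with 0 of 19 passing and 1 fallen when adjusted over the list alone (adjusted p = 0.000184, and adjusted p = 0.312 with an estimated correlation). The 5 measured adipocyte genes had a median of -0.54, with 0 passing and 4 fallen when adjusted over the list alone (adjusted p = 0.00545, and adjusted p = 0.291 with an estimated correlation). Ribosomal protein genes had a median of -0.12, with 0 of 26 passing in either adjustment (adjusted p = 0.0182, and adjusted p = 0.831 with an estimated correlation). The 9 mitochondrially encoded genes listed were all higher, with 0 passing and 8 risen when adjusted over the list alone (median 0.48, mean 1.52, adjusted p = 5.3e-07, and adjusted p = 0.312 with an estimated correlation). Their median ratio to the control was 0.70, 0.69 and -0.03 at days 0, 3 and 5, and in the day 0 library of the Cry2 knockdown alone, mt-Co2 and mt-Atp6 had 78.6 and 107 times the median CPM of the other 8 libraries. The sarcomere list, with a median ratio to the control of -0.22, 0.10 and 0.11 at days 0, 3 and 5, did not pass (29 of 50 genes higher, 0 past the threshold, 3 risen and 2 fallen when adjusted over the list alone, median 0.06, adjusted p = 0.676). The G1 call was lost without the day 3 control (adjusted p = 0.158). The DNA replication call was lost without the day 0 library of the Cry2 knockdown or the day 0 or day 3 control (adjusted p up to 0.463). The ribosomal call was lost without the day 5 library of the Cry2 knockdown or the day 0 control (adjusted p up to 0.666).

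Genes of the unfolded protein and amino acid stress response differed between the 3 libraries of day 3. Trib3, a stress-induced pseudokinase gene, had 153 CPM in the control at day 3, 12.5 CPM in the Cry2 knockdown and 64.5 CPM in the Cry1 knockdown, while Asns, asparagine synthetase, had 303, 46.6 and 166 CPM, both genes chosen after their values were seen. At day 5 Trib3 had 127, 210 and 242 CPM in the same order. The median log2 ratio of the 17 genes to the control was -1.56 at day 3 and 0.29 at day 5 in the Cry2 knockdown, and -0.72 and 0.35 in the Cry1 knockdown, all 4 outside the central 95% of matched random lists. In the Cry2 knockdown over the 3 days, 0 of 17 passed in either adjustment, and the list was lower by a median of -0.41 (adjusted p = 0.0349, and adjusted p = 0.831 with an estimated correlation). Without the day 3 control the direction turned (adjusted p = 0.944), and the call was also lost without the day 3 library of the Cry2 knockdown or the day 5 library of the Cry1 knockdown (adjusted p = 0.844 and 0.0547).

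The Cry1 knockdown was compared with the control in the same way. Igfn1, which encodes a protein of the muscle sarcomere, rose by 3.0 ± 0.21 (n = 3 libraries per genotype, adjusted p = 0.000714), from 0.587, 10.2 and 26.1 CPM in the control to 7.86, 75.8 and 198 CPM. Wif1, a secreted inhibitor of Wnt proteins, rose by 3.61 ± 0.50 and Prr32 by 3.55 ± 0.59. Among other rises were Frem2, a matrix protein gene (3.18 ± 0.46), Fgf13 (3.13 ± 0.45) and Iqsec3 (3.07 ± 0.54). The matrix gene Aspn fell by -2.48 ± 0.29, Add2, a cytoskeletal adducin, by -2.04 ± 0.29, and Hdc, histidine decarboxylase, by -1.91 ± 0.24. The growth factor gene Btc fell by -2.92 ± 0.57, the claudin gene Cldn15 by -1.94 ± 0.37 and Sprr1a by -1.90 ± 0.32. Of 13094 genes 122 rose and 227 fell, with 2492 at an unadjusted p under 0.05. Among the named genes, the processed pseudogenes Rpl31-ps11 (-4.95 ± 0.96) and Rpl28-ps3 (-3.36 ± 0.54) are uncertain, because 47.9% and 56.4% of their 50-base words also stand in transcripts of other genes. The count of 349 became 108, 27 and 125 without the day 0, 3 and 5 libraries of the Cry1 knockdown, 82, 71 and 48 without those of the control, and 205 and 221 without the day 3 and day 5 libraries of the Cry2 knockdown. It was 919 with all genes that have a count. In every fit without 1 library, 1 of 18 named genes, Igfn1, passed, while Btc passed in 1 of 7 such fits and Cldn15 in 1 of 9. The filter on low counts took Btc and Prr32 out of some of these fits, so the sizes of their folds are uncertain.

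Sarcomere genes were higher together in the Cry1 knockdown, most of all at day 0. Of 50 measured, 48 were higher, 4 rose over all genes and 27 rose when adjusted over the list alone, with a median of 0.66 (adjusted p = 3.1e-22, and adjusted p = 0.468 with an estimated correlation). The 4 were Mybpc2, a myosin-binding protein (2.0 ± 0.21), Myh7, a slow myosin heavy chain (1.06 ± 0.21, with 28.2% of its 50-base words in other transcripts), Nrap (0.75 ± 0.15) and Actn3, a muscle actinin (0.56 ± 0.08). The median ratio to the control was 1.35 at day 0, 0.67 at day 3 and 0.23 at day 5. At day 0, among genes chosen after their values were seen, Acta1, skeletal muscle actin, had 364 CPM in the Cry1 knockdown, 117 CPM in the control and 72.5 CPM in the Cry2 knockdown, and Myog, the transcription factor myogenin, had 180, 58.7 and 35.4 CPM. Calcium handling and excitation-contraction coupling genes had a median of 0.50, with 2 of 16 risen, Pvalb, a calcium buffer (2.98 ± 0.41) and Trdn, triadin (1.63 ± 0.19), and 9 risen when adjusted over the list alone (adjusted p = 7.4e-08, and adjusted p = 0.468 with an estimated correlation). Muscle energy metabolism genes had a median of 0.25, with Ckm, muscle creatine kinase (0.84 ± 0.18), and Pgam2, a glycolytic mutase (0.79 ± 0.12), risen of 17 and 4 risen when adjusted over the list alone (adjusted p = 7.9e-05, and adjusted p = 0.468 with an estimated correlation). Cholesterol synthesis genes were higher in 20 of 21 cases with a median of 0.36, where 1 rose and 2 rose when adjusted over the list alone (adjusted p = 2.0e-05, and adjusted p = 0.742 with an estimated correlation). Their median ratio was -0.15 at day 0, 0.43 at day 3 and 0.70 at day 5. These 4 list calls were kept in all 9 fits without 1 library. The lists of myoblast fusion (adjusted p = 0.598) and of acetylcholine receptor and synapse genes (adjusted p = 0.226) did not pass.

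Clock output and matrix genes went both ways in the Cry1 knockdown, while the genes of the growth factor axis past the threshold fell. Per2, a clock repressor under E-box control, rose by 1.44 ± 0.17 and Tef, a clock output factor, by 0.51 ± 0.10, while Nr1d1, which encodes the repressor REV-ERB alpha, fell by -0.55 ± 0.12 (n = 3). In the list of E-box clock repressors and outputs 2 of 11 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone (median 0.13, adjusted p = 0.0493, and adjusted p = 0.468 with an estimated correlation). In the insulin-like growth factor axis Igf1 fell by -1.85 ± 0.22 and Igfbp6 by -0.52 ± 0.11, 2 of 13, with 3 fallen and 1 risen when adjusted over the list alone (median -0.23, adjusted p = 0.0472, and adjusted p = 0.636 with an estimated correlation). Dcn, the matrix proteoglycan decorin, fell by -1.31 ± 0.13 and the collagen gene Col6a3 by -1.14 ± 0.17, while Col1a1 rose by 0.75 ± 0.14. The extracellular matrix and fibroblast list as a whole did not pass by camera (adjusted p = 0.325) but was lower by fry (adjusted p = 0.0490), with 3 risen and 5 fallen of 22 when adjusted over the list alone. Mef2c, a myogenic transcription factor, rose by 1.23 ± 0.19 in a list that did not pass (adjusted p = 0.538). Igf1 carries in its 3' UTR at least 1 of the words TAACATA and CTAACAT, which Aspn, Add2, Hdc, Btc, Cldn15, Sprr1a, Dcn, Col6a3, Igfbp6 and Nr1d1 lack, and Mef2c and Trdn, which rose, carry at least 1 too. At least 1 of the words stands in 35.4% of the searched genes called lower, 13.7% of those called higher and 15.0% of all genes searched. These words were also picked out on the same fold changes, so the shares are no separate check. DNA replication genes had a median of 0.11 with 0 of 30 passing in either adjustment (adjusted p = 0.0493, and adjusted p = 0.851 with an estimated correlation). The mitosis list did not pass (adjusted p = 0.753). Calls were lost without the day 0 or 3 libraries of both knockdowns or the day 0 control for the E-box list (adjusted p up to 0.218). The growth factor call was lost without the day 3 or 5 library of the Cry1 knockdown, the day 0 library of the Cry2 knockdown or the day 5 control (adjusted p up to 0.219). The DNA replication call was lost without the day 0 or 5 library of the Cry1 knockdown, the day 0 or 3 library of the Cry2 knockdown or the day 5 control (adjusted p up to 0.493).

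**Figure D2:**
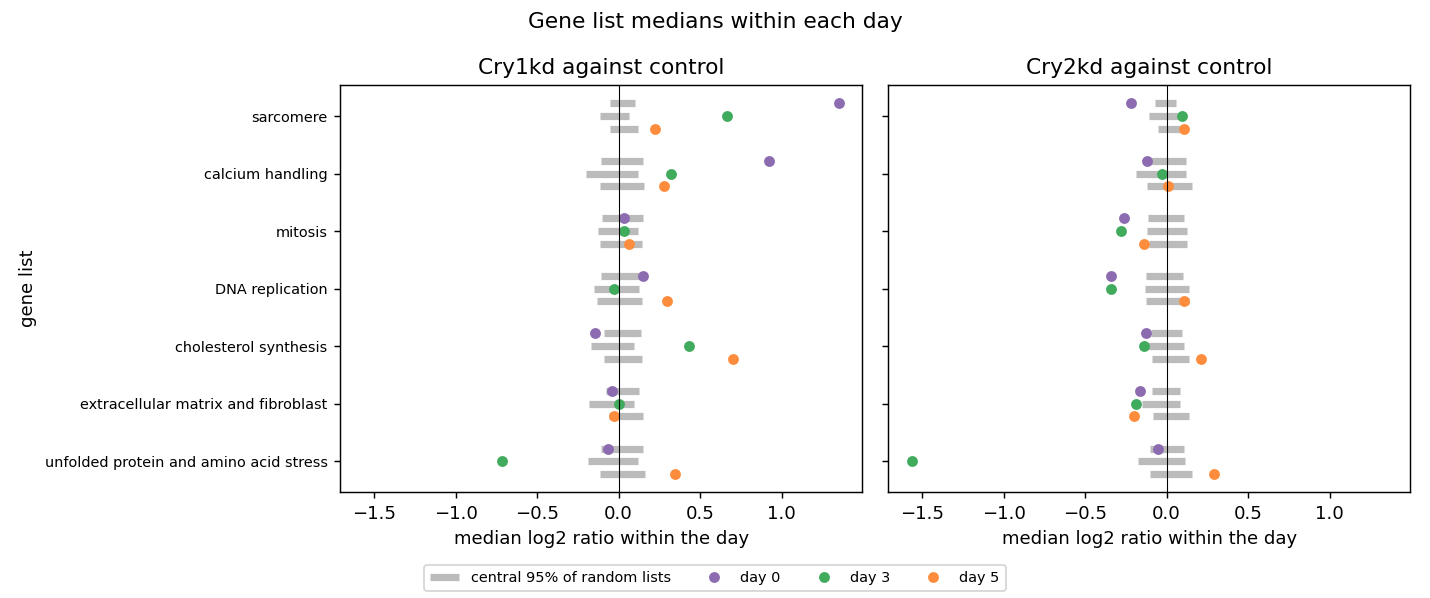
Median log2 ratio of 7 gene lists to the control library of the same day (horizontal axis), for the Cry1 knockdown and the Cry2 knockdown, with 1 point per list and day. Grey bars give the central 95% of 10000 random lists matched on size and expression. Sarcomere genes in the Cry1 knockdown lie at 1.35, 0.67 and 0.23 on days 0, 3 and 5.

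The Cry2 knockdown against the Cry1 knockdown asks where the losses of the cryptochromes differ, without use of the control libraries as reference. Col23a1 was higher in the Cry2 knockdown by 3.29 ± 0.28 (n = 3 libraries per genotype, adjusted p = 0.00126) and Vtn, the matrix protein vitronectin, by 4.74 ± 0.85. Other genes higher there were Cacng7 (3.70 ± 0.53), Dnaic1 (3.02 ± 0.72), Cpa4 (2.93 ± 0.56) and Btc (2.79 ± 0.59). Lower were Frem2 (-4.92 ± 0.57), Prr32 (-4.13 ± 0.65), the collagen gene Col11a1 (-4.04 ± 0.46), Iqsec3 (-3.64 ± 0.60) and Nrk (-3.52 ± 0.47). Vtn, Cacng7, Dnaic1, Btc, Prr32 and Nrk were tested in only 7 of the 9 fits without 1 library. The filter on low counts took them out of the rest, so the sizes of their folds are uncertain. In all 555 genes rose and 483 fell in the Cry2 knockdown against the Cry1 knockdown, with 3375 at an unadjusted p under 0.05. Bclaf1 fell by -0.29 ± 0.07 (adjusted p = 0.0412) and Tmem176b by -2.80 ± 0.40 (adjusted p = 0.00601). Uncertain for shared 50-base words are Rps27a-ps2 (-11.62 ± 2.54, 99.5% shared, and 0 CPM in all Cry2 knockdown libraries, so that its value depends on the prior count) and Rpl31-ps11 (5.20 ± 0.94). The value of mt-Atp8 (4.54 ± 1.16) rested on the day 0 library of the Cry2 knockdown, without which it was 0.99. The count of 1038 became 572, 258 and 373 without the day 0, 3 and 5 libraries of the Cry1 knockdown and 552, 349 and 401 without those of the Cry2 knockdown, and it was 660 with DESeq2. Without 1 library the value of Frem2 ran from -7.82 to -4.39 and that of Prr32 from -7.55 to -3.45. Vtn was lost without the day 3 or 5 library of the Cry1 knockdown (adjusted p up to 0.0964). Iqsec3 was lost without the day 0 or 3 library of the Cry2 knockdown (adjusted p up to 0.0643). Cpa4 was lost without the day 5 library of either or the day 3 library of the Cry2 knockdown (adjusted p up to 0.108, values from 1.97 to 3.77). Dnaic1 was lost in all but 1 of 7 fits, without the day 3 or 5 library of the Cry1 knockdown, the day 0 or 5 library of the Cry2 knockdown or the day 0 or 5 control (adjusted p up to 0.14, values from 2.05 to 4.49). Btc was kept in 2 of 7 fits and lost without any library of the Cry1 knockdown or the day 3 or 5 library of the Cry2 knockdown (adjusted p up to 0.14). The Bclaf1 call was kept in 1 of the 9 fits without 1 library, that without the day 3 control, and 10 of 21 named genes passed in every fit.

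Sarcomere, calcium handling, muscle energy metabolism, DNA replication and mitosis genes were lower as lists in the Cry2 knockdown than in the Cry1 knockdown. The lists of myogenic transcription factors (adjusted p = 0.369), myoblast fusion (adjusted p = 0.271), acetylcholine receptor and synapse genes (adjusted p = 0.452) and G1 cyclins, kinases and E2Fs (adjusted p = 0.0596) did not pass. In the sarcomere list 11 of 50 genes fell and 1 rose, with 22 fallen and 2 risen when adjusted over the list alone (median -0.61, adjusted p = 1.2e-13, and adjusted p = 0.502 with an estimated correlation). Examples are Myh8, a perinatal myosin (-2.28 ± 0.34), Actn2 (-1.71 ± 0.25) and Mybpc1 (-1.73 ± 0.24). In calcium handling 7 of 16 fell, and 8 when adjusted over the list alone (median -0.60, adjusted p = 6.6e-06, and adjusted p = 0.494 with an estimated correlation). In muscle energy metabolism 4 of 17 fell, among them Ampd1, muscle AMP deaminase (-2.64 ± 0.59), and 7 when adjusted over the list alone (median -0.25, adjusted p = 0.00366, and adjusted p = 0.502 with an estimated correlation). In DNA replication 5 of 30 fell, among them the helicase gene Mcm10 (-0.75 ± 0.15) and the licensing factor Cdt1 (-0.73 ± 0.15), and 10 when adjusted over the list alone (median -0.30, adjusted p = 4.7e-05, and adjusted p = 0.637 with an estimated correlation). In mitosis 3 of 29 fell, Foxm1, a cell cycle transcription factor (-0.72 ± 0.14), and the kinesins Cenpe (-0.45 ± 0.11) and Kif11 (-0.40 ± 0.09), and 5 when adjusted over the list alone (median -0.29, adjusted p = 5.5e-05, and adjusted p = 0.494 with an estimated correlation). In the adipocyte list 2 of 5 fell, also over the list alone, the fatty acid carrier Cd36 (-2.22 ± 0.29) and the lipase Lpl (-0.74 ± 0.15), with adjusted p = 0.00966, and adjusted p = 0.494 with an estimated correlation. Cholesterol synthesis had 1 of 21 fallen, also over the list alone (median -0.37, adjusted p = 0.000265, and adjusted p = 0.652 with an estimated correlation). Ribosomal proteins had 0 of 26 passing in either adjustment (median -0.18, adjusted p = 0.00379, and adjusted p = 0.652 with an estimated correlation), a call lost without the day 5 library of either knockdown (adjusted p up to 0.176).

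The day comparisons describe differentiation common to the 3 genotypes. From day 0 to day 3, Fmod, the matrix protein fibromodulin, rose by 7.20 ± 0.52 (n = 3 libraries per day), and Scara5, a scavenger receptor gene, went from 0 CPM in every library to 16.8, 2.12 and 8.9 CPM in the Cry1 knockdown, the Cry2 knockdown and the control, with Fam78a, Isx, Trpv1, Ptgds, Mybpc1 and Otud7a also among the largest rises. The chemokine gene Cxcl5 fell by -6.99 ± 0.41 and Il1rn, the interleukin receptor antagonist, by -5.89 ± 0.39, with Prl2c2, Car8, Itgb7, Csn3, Shank2 and Prl2c3 also among the largest falls. The paralogs Prl2c2 and Prl2c3 share 85.6% and 78.6% of their 50-base words with other transcripts. In all 3326 genes rose and 3361 fell. By day 5, 3712 genes rose and 3647 fell against day 0, and the largest rises held the muscle genes Mybpc1 (9.25 ± 0.36), Myot and Myl2 (at least 27.8-fold and 25.4-fold higher) beside Scara5 (at least 86.5-fold higher), Gdf5, Hsd17b13, Otud7a and Tnr. The largest falls at day 5 were of Prl2c2, Igsf5, Il1rn, Ptprn, Itgb7, Prl2c3, Nefl and Dmbx1, between -8.61 and -5.52. Exons of other genes overlap 40.3% of the exon bases of Gdf5 and 32.8% of those of Nefl. Scara5, Myot and Myl2 had 0 counts in all 3 libraries of day 0, so their folds are bounds against a floor of 3 counts per library.

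Sarcomere genes rose together and cell division genes fell together from day 0 to day 5. Of 50 sarcomere genes 49 rose and 1 fell (median 5.34, or 5.32 with the 2 members at 0 on day 0 set to their bound, adjusted p = 4.9e-59, and 0.0409 with an estimated correlation), and all 16 calcium handling genes rose (median 4.70, adjusted p = 4.8e-33), among them Casq1, calsequestrin (8.19 ± 0.26). All 10 acetylcholine receptor and synapse genes rose (median 2.10, adjusted p = 1.8e-07), as did 16 of 17 energy metabolism genes (median 5.39, adjusted p = 3.0e-20). All 29 mitosis genes fell (median -3.46, adjusted p = 1.9e-77), among them Ccnb1, cyclin B (-4.08 ± 0.15), and all 30 DNA replication genes (median -2.87, adjusted p = 1.8e-39). Of 22 extracellular matrix genes 16 rose and 4 fell (median 1.60, adjusted p = 1.9e-08), with Postn, periostin, at 5.61 ± 0.36 and Dcn at 5.02 ± 0.15. These 7 calls also passed with an estimated correlation, and the counts adjusted over the list alone were the same. Calls lost with an estimated correlation were those of muscle atrophy, with 6 of 8 risen (adjusted p = 0.000642, and adjusted p = 0.188 with an estimated correlation), and of the G1 list, with 7 of 11 fallen and 2 risen (adjusted p = 0.00675, and adjusted p = 0.275 with an estimated correlation). The others so lost were immediate early genes, with 11 of 19 fallen and 3 risen (adjusted p = 0.0078, and adjusted p = 0.298 with an estimated correlation), mitochondrially encoded genes, with 6 of 9 risen (median 1.29, mean 0.05, adjusted p = 0.0111, and adjusted p = 0.441 with an estimated correlation), and myogenic transcription factors, with 7 of 11 risen and 3 fallen (adjusted p = 0.0322, and adjusted p = 0.275 with an estimated correlation). The E-box clock list had 8 of 11 risen and 1 fallen (adjusted p = 0.0322, and adjusted p = 0.188 with an estimated correlation), the growth factor axis 7 of 13 risen and 3 fallen (adjusted p = 0.035, and adjusted p = 0.32 with an estimated correlation), and ribosomal proteins 15 of 26 fallen (adjusted p = 0.035, and adjusted p = 0.7 with an estimated correlation). For these 8 lists the counts over the list alone were again the same. The calls of myogenic factors without the day 0 control (adjusted p = 0.0593), of the growth factor axis without the day 0 or 5 control (adjusted p up to 0.0969), and of ribosomal proteins without the day 0 or 5 library of the Cry2 knockdown or the day 0 control (adjusted p up to 0.108) were lost.

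At day 5 against day 0 the remaining lists did not pass by camera. By fry, 8 of them had adjusted p from 0.000302 to 0.0395: myoblast fusion, CDK inhibitors, other clock genes, smooth muscle, adipocyte, p53 targets, the stress response and oxidative phosphorylation. By camera, adjusted p was 0.139 for myoblast fusion (median -0.06, mean 0.82), in which Mymk and Mymx, the fusion proteins myomaker and myomixer, rose by 4.48 ± 0.30 and 4.52 ± 0.25. It was 0.58 for CDK inhibitors and pocket proteins, where Cdkn1a, the inhibitor p21, rose by 2.26 ± 0.11, 0.418 for other clock genes, 0.392 for reserve cell and Notch genes, and 0.114 for smooth muscle and TGF-beta or YAP targets. It was 0.0839 for adipocyte genes, where Cd36 rose by 6.88 ± 0.41, 0.951 for interferon response (median -0.12, mean -0.04, test upward), 0.392 for p53 targets and 0.0717 for the stress response. Adjusted p was 0.569 for cholesterol synthesis, 0.4 for oxidative phosphorylation and 0.58 for glycolysis and hypoxia. Osteoblast genes, with 3 measured members, and endothelial and blood cell genes, with 2, were not tested, and Spp1 and Runx2 of the osteoblast list fell by -3.56 ± 0.35 and -0.57 ± 0.12.

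Day 5 was also compared with day 3. The acetylcholine receptor subunit gene Chrne rose by 3.42 ± 0.49 (n = 3 libraries per day, adjusted p = 0.00339), Dmd, dystrophin, by 3.23 ± 0.42 and the nuclear receptor gene Esrrg by 3.84 ± 0.65, with Scel, Hsd17b13, Col25a1, Mrvi1 and Tfcp2l1 also among the largest rises. Cdkn1c, a CDK inhibitor with 30.7% of its exon bases overlapped by Gm44732, fell by -3.48 ± 0.30, with Fbxl13, Rmi2, Gzme, Aunip, Gpr35, Igsf5 and the pseudogene Rpl13-ps1 also among the largest falls. Of 21 cholesterol synthesis genes 17 fell and 1 rose, and 18 and 1 when adjusted over the list alone (median -0.74, adjusted p = 2.1e-10, and adjusted p = 0.301 with an estimated correlation), after 11 had risen and 1 fallen from day 0 to day 3. Of 50 sarcomere genes 26 rose, and 32 when adjusted over the list alone (median 0.73, adjusted p = 3.5e-14, and adjusted p = 0.294 with an estimated correlation). All 29 mitosis genes fell (median -1.14, adjusted p = 1.9e-30, and 0.0446 with an estimated correlation), the only list to pass there. Of 30 DNA replication genes 26 fell, and 27 when adjusted over the list alone (median -1.05, adjusted p = 8.1e-21, and adjusted p = 0.154 with an estimated correlation). Of 26 oxidative phosphorylation genes 14 fell, and 18 over the list alone (median -0.33, adjusted p = 3.3e-06, and adjusted p = 0.301 with an estimated correlation). Of 26 ribosomal protein genes 11 fell, and 13 over the list alone (median -0.30, adjusted p = 0.000266, and adjusted p = 0.423 with an estimated correlation). Further lists called higher were calcium handling (12 of 16 rose), muscle energy metabolism (10 of 17), synapse (6 of 10, with 1 fallen), extracellular matrix (14 of 22, with 2 fallen), adipocyte (3 of 5) and other clock genes (4 of 10). Called lower were G1 (4 of 11 fell) and glycolysis genes (9 of 20, with 3 risen). For these 8 lists adjusted p ran from 3.0e-11 to 0.0285, and adjusted p from 0.154 to 0.387 with an estimated correlation. The G1 call was lost without the day 3 control (adjusted p = 0.0571). That of other clock genes was lost without the day 3 or day 5 library of the Cry1 knockdown (adjusted p = 0.0716 and 0.162). In all 1923 genes rose and 1730 fell. The count of 3653 became 2161 and 2108 without the day 3 and 5 libraries of the Cry1 knockdown and 2045 and 2252 without those of the Cry2 knockdown, and it was 2382 with DESeq2. Of 17 named genes 12 passed in every fit without 1 library. The Igsf5 call was lost without any library of the Cry1 knockdown, the day 5 library of the Cry2 knockdown or the day 3 or 5 control (adjusted p up to 0.134). That of Tfcp2l1 was lost without the day 5 library of the Cry1 knockdown (adjusted p = 0.0527). The Fbxl13 call was lost without the day 3 or 5 library of the Cry2 knockdown or the control (adjusted p up to 0.0929, values from -6.29 to -2.58). That of Rmi2 was lost without the day 3 library of the Cry1 knockdown, the day 5 library of the Cry2 knockdown or the day 3 or 5 control (adjusted p up to 0.0839, values from -5.60 to -2.49).

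A separate interaction fit of 13608 genes asked whether the change from day 0 to days 3 and 5 differed between a knockdown and the control. Each genotype has 1 library at day 0, which this fit reproduces exactly, so its spread comes from days 3 and 5 alone. Each response and its p-value thus rest on single day 0 libraries, and could not be checked without them. In the Cry1 knockdown the sarcomere list had a smaller rise than in the control, with 41 of 51 genes lower, 0 passing and 20 fallen when adjusted over the list alone (median -0.92, adjusted p = 4.8e-21, and adjusted p = 0.431 with an estimated correlation). Myog had a response of -1.47 ± 0.18 (adjusted p = 0.131) and Rbm24, an RNA-binding protein gene of muscle, of -2.11 ± 0.24 (adjusted p = 0.111), neither past the threshold, from day 0 levels of 180 and 38.1 CPM in the Cry1 knockdown and 58.7 and 5.87 CPM in the control. Cholesterol synthesis genes had a higher response than in the control in 21 of 21 cases, with 0 passing and 8 risen when adjusted over the list alone (median 0.65, adjusted p = 4.1e-23, and adjusted p = 0.391 with an estimated correlation). The growth factor axis had a median of -0.48, with 0 of 13 passing and 3 fallen when adjusted over the list alone (adjusted p = 3.1e-05, and adjusted p = 0.391 with an estimated correlation). Lower by the list test were also myogenic transcription factors, myoblast fusion, calcium handling, acetylcholine receptor and synapse, reserve cell and Notch, smooth muscle and mitochondrially encoded genes. Higher were interferon response, oxidative phosphorylation, ribosomal protein and glycolysis genes. In these 11 lists 0 genes passed, with adjusted p from 2.6e-06 to 0.0107, and adjusted p from 0.391 to 0.596 with an estimated correlation. The synapse, interferon and ribosomal calls were lost without the day 5 library of the Cry1 knockdown (adjusted p = 0.131, 0.0712 and 0.0755). Glycolysis was lost without the day 5 control (adjusted p = 0.143). Without either of these libraries the smooth muscle (adjusted p = 0.161 and 0.327) and mitochondrial calls (adjusted p = 0.0544 and 0.601) were lost. The other genes of lowest p, none past the threshold, were Igfbp2 (-1.47 ± 0.19), Phb (1.96 ± 0.22, with 41.1% of its 50-base words in other transcripts) and the pseudogene Ldha-ps (8.65 ± 0.75). No gene passed with edgeR in the Cry1 knockdown response, where 670 had an unadjusted p under 0.05 and DESeq2 called 21. That count of 0 became 126 without the day 3 control, 109 without the day 5 control, 2 without the day 3 or the day 5 library of the Cry1 knockdown and 1 without the day 5 library of the Cry2 knockdown.

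In the Cry2 knockdown response 5 genes passed. The mitochondrially encoded genes mt-Atp6 (-7.35 ± 0.35), mt-Co3 (-6.98 ± 0.34), mt-Co2 (-6.67 ± 0.36) and mt-Atp8 (-6.47 ± 0.52) had high counts in the Cry2 knockdown at day 0. There mt-Co2 had 3784 counts, against 28 to 61 in the other 8 libraries. Of the 50-base words of mt-Co2, mt-Co3 and mt-Atp6, 100%, 99.9% and 99.5% also stand in transcripts of other genes, and of mt-Atp8 0%. Gm15464, which rose, had 104 CPM in the control at day 0, 14.0 and 23.4 CPM in the Cry2 knockdown at days 3 and 5, and 0.177 CPM or less in the other 6 libraries. In the mitochondrially encoded list 3 of 9 fell, also over the list alone (median -0.41, mean -2.47, adjusted p = 1.3e-44, and adjusted p = 0.759 with an estimated correlation). Reserve cell and Notch genes had a median of -0.33, with 0 of 13 passing and 3 fallen when adjusted over the list alone (adjusted p = 0.000605, and adjusted p = 0.759 with an estimated correlation). Immediate early genes had a median of -0.39, with 0 of 20 passing and 1 fallen when adjusted over the list alone (adjusted p = 0.00102, and adjusted p = 0.759 with an estimated correlation). Sarcomere genes had a higher response than in the control in 37 of 51 cases, with 0 passing in either adjustment (median 0.33, adjusted p = 0.00535, and adjusted p = 0.835 with an estimated correlation). DNA replication genes, which fall with differentiation, had a smaller fall in 23 of 30 cases, with 0 passing and 1 risen when adjusted over the list alone (median 0.16, adjusted p = 0.00744, and adjusted p = 0.759 with an estimated correlation). Oxidative phosphorylation (24 of 26 higher, median 0.14, adjusted p = 0.0309) and smooth muscle genes (10 of 15 higher, median 0.17, adjusted p = 0.0435) had 0 passing in either adjustment, and for both adjusted p = 0.759 with an estimated correlation. Without the day 5 library of the Cry2 knockdown the sarcomere, DNA replication and oxidative phosphorylation calls were lost (adjusted p = 0.0769, 0.0925 and 0.0925). The sarcomere call was also lost without the day 3 control (adjusted p = 0.0931) and the DNA replication call without the day 5 control (adjusted p = 0.441). Smooth muscle was lost without the day 3 library of the Cry2 knockdown (adjusted p = 0.278). It turned without the day 3 control (adjusted p = 0.742). The count was 818 at an unadjusted p under 0.05 and 11 with DESeq2, and it was 0 without mitochondrially encoded genes and pseudogenes. It was 91 and 160 without the day 3 and day 5 controls, and the mt-Atp8 call was lost without the day 3 or 5 library of the Cry2 knockdown (adjusted p up to 0.125).

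**Figure D3:**
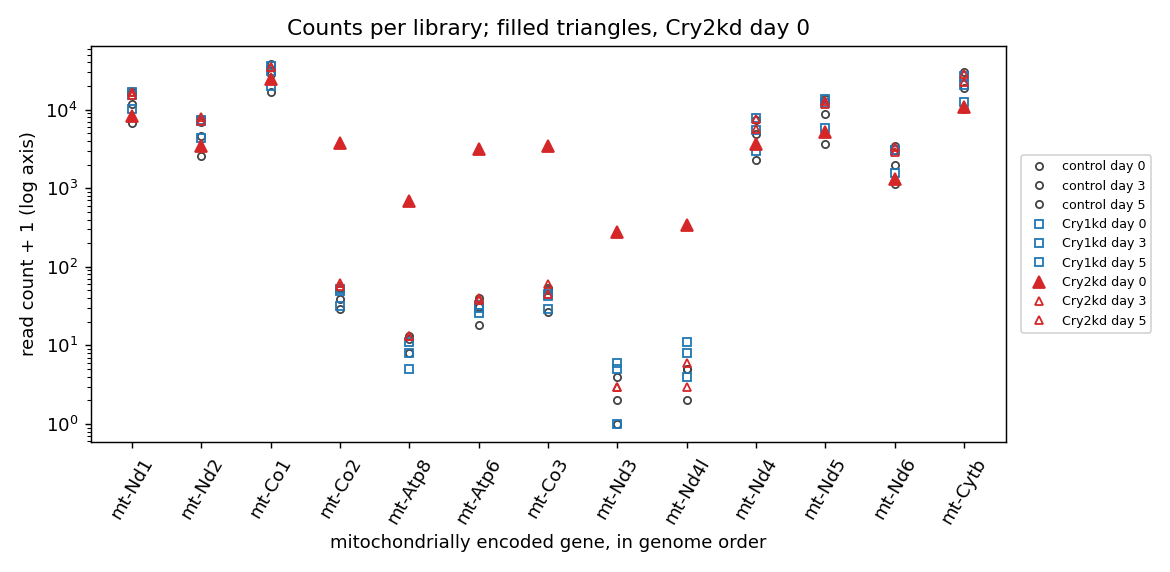
Read counts plus 1 (log axis) of the mitochondrially encoded protein genes in genome order, with 1 symbol per library. In the Cry2 knockdown at day 0 (filled triangles) the genes from mt-Co2 to mt-Nd4l lie far above the other 8 libraries, with 3784 counts for mt-Co2, while mt-Nd1 and mt-Cytb, with 8186 and 10955 counts, do not.

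The calls of the knockdowns against the shared control were compared with each other. Among 11 and 349 genes called with edgeR, 0 were called in both, whether in the same or the opposite direction. Across the 12378 genes with an average log2 CPM above 1, which are not independent replicates, 56.2% of log2 fold changes had the same sign in both knockdowns. Unchanged knockdowns simulated against shared control libraries gave 66.6% (65.8% to 67.3% in 20 simulations). Those control libraries were themselves simulated from the mean of each day, so traits of the real ones are absent from them. The correlation of the log2 fold changes was 0.185, below the simulated 0.495 (0.472 to 0.509), while their covariance was 0.0273, above the simulated 0.0245 (0.0229 to 0.0259). Independent lists with as many calls as fall among those 12378 genes would share 0.0562 genes called higher and 0.0917 called lower. The number of genes called in the same direction was 45 with all genes that have a count and 8 with DESeq2, and it was 1 without the day 0 library of either knockdown and 2 without the day 0 control.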

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

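The test for more mitochondrial RNA was chosen only after the result was seen. By the interaction test, 5 genes differed in their differentiation response between the Cry2 knockdown and the control. Gm15464 had a fitted response of 22.02 (log2), which is no measure of size because most of its libraries have no counts. The others were mt-Atp6 at -7.35, mt-Co3 at -6.98, mt-Co2 at -6.67 and mt-Atp8 at -6.47.

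In the Cry2 knockdown at day 0, 6 neighbouring mitochondrially encoded genes from mt-Co2 to mt-Nd4l (chromosome M, 7013 to 10173) had at least 10 times the median level of the other 8 libraries. Of the mitochondrially encoded genes, 12 have under 50% of their 50-base words in another gene, mt-Atp8 among them. Their median log2 ratio to the day 0 control was 0.504, somewhat higher as a set, against 7.19 for mt-Co2. More mitochondrial RNA in that library as the cause of the whole rise is thereby argued against, while a smaller general rise is not. Over 153 other genes with at least 90% of their words in another gene, the median was -0.029 (quartiles -0.235 and 0.333). That argues against a general counting, in that library alone, of reads that match several genes. A median cannot exclude such a change at some loci. In the other 8 libraries mt-Co2 had 28 to 61 counts, and mt-Co1, with 51.1% of its words shared, 16557 to 38191. Whether the 6 genes are low in those libraries rather than high in this one was not tested. Reads shared with a near-identical nuclear copy may account for the pattern and stay open, since 5 of the 6 raised genes have at least 90% of their words in another gene. The remaining one, mt-Atp8, has 0% and met the bound written beforehand against this explanation. That bound was set aside after the value was seen. The reason was that copies outside the longest annotated transcripts were not searched and that mt-Atp8 lies between mt-Co2 and mt-Atp6. Apart from more mitochondrial RNA in that library, no biological explanation was tested.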

How the results depend on the processing

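The fits without mitochondrially encoded genes and pseudogenes were chosen only after the data were seen. Size factors by RLE left every count of genes within 1.5 times its value, and the counts for day 3 and day 5 against day 0 stayed within that range under every alternative run. Of alternatives to 87 called lists, 830 list values kept direction and side of the threshold, 164 lost the call and 2 turned. Response fits without the day 0 library of the knockdown or the control could not be estimated.

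For the Cry2 knockdown against the control, the count of 11 became 316 with no filter, 6 with at least 1 CPM in 3 libraries, 90 with DESeq2, 0 with no day term, 5 with only the 6 libraries compared, 23, 2 and 0 without days 0, 3 and 5, and 19 without mitochondrially encoded genes and pseudogenes. Leaving out 1 library gave 0 to 17. For the Cry1 knockdown against the control, 349 became 919 with no filter, 0 with no day term, 203 with 6 libraries and 69, 16 and 45 without days 0, 3 and 5, with 27 to 366 without 1 library. Between the knockdowns, 1038 became 660 with DESeq2, 0 with no day term and 508, 126 and 229 without days 0, 3 and 5, with 258 to 1137 without 1 library. With no day term, differences between days enter the spread, and without a day or the third genotype there are fewer libraries.

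For day 5 against day 3, the count became 2382 with DESeq2, 2190 with no genotype term, 1553 without the Cry1 knockdown and 1835 without the Cry2 knockdown, with 2045 to 3739 without 1 library. The Cry2 knockdown response became 48 with no filter, 11 with DESeq2 and 0 without mitochondrially encoded genes and pseudogenes, with 5 to 160 without 1 library. The Cry1 knockdown response became 72 with no filter and 21 with DESeq2, with 0 to 126 without 1 library. Lists called were 14 with an estimated correlation against 87. Genes called in both knockdowns became 45 with no filter, 8 with DESeq2, 3 without day 0 and 1 without mitochondrially encoded genes and pseudogenes, with 0 to 2 without 1 library. The unfolded protein and amino acid stress list in the Cry2 knockdown ran from adjusted p = 4.0e-07 to 0.944 without 1 library, and it turned without the day 3 control. The smooth muscle list in the Cry2 knockdown response turned without the day 3 control (adjusted p = 0.742, range over its alternatives 1.4e-06 to 0.844). Where construction does not show it, the cause was not tested.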

Other observations

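The seed word checks by day and in the other knockdown, the count without seed words and the splits were chosen only after the results were seen. At day 3, further genes of the amino acid stress response, chosen after their values were seen, ran in the order of control, Cry1 knockdown and Cry2 knockdown. Chac1, a glutathione-degrading enzyme gene, had 194, 66.2 and 24.8 CPM and Atf4, a transcription factor of that response, 807, 481 and 314 CPM. At day 5 Chac1 had 95.5, 226 and 215 CPM in the same order. With 1 library each, these values describe these libraries only.

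Sarcomere genes were higher in the Cry1 knockdown than in the control at day 0. GC content or gene length bias is argued against, since the sarcomere median kept 102% of its size (1.35 before, 1.38 after) once their trend was removed. A culture further along differentiation at day 0 may account for part of it, since genes that rose at least 2-fold by day 3 in the Cry2 knockdown had a median log2 ratio of 0.177 (1436 genes) and those that fell -0.015 (1219 genes), the latter small, both beyond all 1000 matched random sets. Other lists called higher by day 5 went with it, with 0.92 for calcium handling, 0.28 for acetylcholine receptor and synapse and 0.26 for myogenic transcription factors. Against that, lists that fall with differentiation were not lower (DNA replication 0.15, mitosis 0.03, G1 0.21). Muscle energy metabolism, which rose by a median of 3.23 by day 3, had 0.07, and extracellular matrix and fibroblast genes, which also rose, had -0.04. The explanation stays open, and an effect of the Cry1 knockdown itself was not tested apart from it, since there is 1 culture.

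More genes were called lower than higher in the Cry1 knockdown. Off-target seed matches of the knockdown sequence may account for part of it. Of all 7-base words only TAACATA (z = -5.83, and -4.87, -4.39 and -4.99 at days 0, 3 and 5) and CTAACAT (z = -4.48) passed the limit of -4.24. Both stand in the Cry1 transcript, where 16.2% of all words do. They overlap there, at positions 1036 and 1035, and so mark 1 site. Genes with these words had mean log2 shifts of -0.07 and -0.053, adjusted for 3' UTR length, GC content and expression. In the Cry2 knockdown the z of these words was 0.48 and 0.63. That matches to these words in the searched 3' UTRs make up the whole excess is argued against. Genes without a word were called lower 1.43 times as often as higher (144 and 101). Of genes with a word, 79 were called lower and 16 higher, though the words were picked out on the same fold changes. Other matches and indirect effects were not searched, and the knockdown sequence is not known. Off-target effects as the whole excess therefore stay open. In the Cry2 knockdown the words TCAGCCC (z = -5.88) and CAGCCCA (z = -4.95), which overlap in sequence, passed the limit of -4.41. Genes with them had mean shifts of -0.047 and -0.036. An effect of losing each cryptochrome stays open too.

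With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 11 genes for the Cry2 knockdown against the control, 349 for the Cry1 knockdown and 1038 between the knockdowns, and the highest other split gave 4, 2 and 1. For days 3 and 5 against day 0 and day 5 against day 3, the real splits gave 6687, 7359 and 3653 genes and the highest other 0. Most of the other splits were not balanced over days, or over genotypes in the day comparisons. Any difference between the real groups enters the spread of a mixed split, so few calls there were largely fixed beforehand. The other splits therefore say nothing about the cause of the calls.

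Of 306 processed pseudogenes above 10 CPM in some library, 25 (8.17%) were under 0.3 CPM in at least 2 others, against 78 of 10166 other genes (0.77%).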
